A study of Drosophila melanogaster with 2 samples.

How the data were processed

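Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos collected at 0 to 24 h. The flies carried Ravus fused to enhanced green fluorescent protein (eGFP), and the fusion protein was precipitated with an antibody against GFP, per the labels. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The series holds 1 group of 2 samples, which the labels number as separate biological replicates of the same strain, and no second condition. The labels do not give the sex of the embryos.

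The authors deposited 8 peak lists on the dm6 assembly. Each replicate has a ranked list and a thresholded list made from that library alone, per the file list that accompanies each sample. The series has a pair of ranked lists made from both replicates, and from these a conservative list and a further thresholded list. The lists were ordered by the irreproducible discovery rate (IDR), a measure of how well the rank of a peak is repeated between a pair of input lists. In the deposited lists the signal is the peak caller's value for each peak, and its scale is not given in the sources used here. The deposited score is a whole number computed from the IDR, between 830 and 1000 in the conservative list. The authors' ranked lists also hold the −log10 of the IDR, capped at 5. Every deposited thresholded peak lay within an IDR limit of 0.01, a −log10 value of 2. The aligner, the peak caller and their versions are not given in the sources used here. The thresholded lists were derived from the alignments and a control, per the file list, and from 1 further input that it does not describe. Read numbers and control values were not analysed here, so the depth of each library is unknown, and a site without a peak cannot be told from a site below the detection limit. Signal was used to rank peaks and compare classes of peaks within a list. Between the replicates' lists it was correlated, and its difference is given only as a description, since their scales need not match.

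The conservative list was the main peak set. Peaks were assigned to the arms 2L, 2R, 3L, 3R, 4, X and Y, and 1472 of its 1474 peaks lay on these. The arm names and lengths were compared with those of the reference sequence before any coordinates were used, and genes came from Ensembl 115 on BDGP6.54, the same dm6 sequence. Coordinates are 1-based. A promoter peak had its summit within 500 bp of an annotated transcription start site, and a distal peak lay over 1000 bp from any. The remaining classes were assigned in the order 5' UTR, CDS, 3' UTR, other exon, intron and intergenic. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error over peaks only.

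Peaks of the replicates were matched by an overlap of at least 1 bp. The overlap was computed with code written for the purpose, and it gave the same counts as bedtools 2.31.1 for both directions, 1196 and 1200. Observed overlaps and feature shares were set against 1000 random placements of the same intervals within their arms. The smallest p these can give is 0.001 one-sided and 0.002 two-sided. Peaks per arm were tested with exact binomial tests against arm length and against the number of start sites. Signal classes, base composition and correlations were tested with 100000 permutations, whose smallest p is 1e-05. Gene lists, motifs and k-mers were tested with two-sided Fisher's exact tests. All families of tests were adjusted by the Benjamini-Hochberg method. A total of 26 gene lists was fixed, of which 25 had members in the annotation, and 8 gene names were matched through synonyms. The microRNA list had no member under its biotype, so it was not tested. Peaks are not biological replicates, and these tests measure spread over sites.

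Sequence was read in windows of 101 bp centred on the summit and compared with windows of the same size centred 300 bp to either side. Windows were searched on both strands for 20 consensus motifs and for all 6-mers and 8-mers. A second background was added after the data had been seen, made of genome windows with the GC count of each peak window and over 1000 bp from any thresholded peak. It held 10 windows per peak, 14711 in all, and 9 windows could not be found. An earlier version with 2 windows per peak was enlarged after its count of enriched 8-mers was seen to vary between draws. These windows exclude soft-masked positions at their centre, whereas 28.7% of the peak summits were soft-masked. They were not matched for distance to start sites.

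The peak set, tests, gene lists, motifs and most of the alternative settings were fixed before the data were examined. The named genes were chosen by a rule fixed at the same time. It takes the gene with the start site nearest to each of the 25 strongest conservative peaks, up to 4 members with the strongest promoter peak from each list with a bound member, and Ravus itself. The alternatives were the other series list, the stronger part of the peaks, each replicate's own list, promoter windows of 250 and 1000 bp, other overlap rules, other sequence windows, and other backgrounds. The background of equal GC, the low-ranked peaks as a comparison for base composition, the return of peaks absent from the conservative list and the alternatives for the Ravus locus were chosen after seeing the data.

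The measurements named below were tested on simulated data made from the real annotation. No simulation was made of the replicate correlation, the rank agreement, the background of equal GC or the 8-mer at other peaks. The divergent regions and the X promoters by GC were not simulated either. For the promoter share, 25.1% was recovered where 25.4% had been built in, over 1472 simulated peaks. For the gene lists, 48 of 48 planted members were recovered over 25 lists, and 0 lists were called without planting. For the chromosome distribution over 1472 peaks, a ratio of 1.42 on X was recovered for a planted 1.38. For the k-mers, an 8-mer planted in 200 of 1472 random windows ranked 1 among 32896, and 0 of 20 draws without planting gave any call. The background there was other random windows, not windows of equal GC. For the 20 motifs, 1 of 20 such draws gave a call. For base composition, 1472 random placements gave a difference of -0.220 percentage points. For the signal by class over 1472 peaks, a planted ratio of 1.5 came back as 1.40. For the replicate overlap, 211 of 1472 peaks were matched where 200 had been planted. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.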

Results

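Ravus-eGFP occupancy was mapped in whole embryos of 0 to 24 h in 2 biological replicates. The study has 1 group, so the questions were which sites the tagged protein occupied, how well the replicates matched, and what genes and sequences lay there. The conservative list held 1474 peaks with a median width of 310 bp, covering 405 kb. The further series list held 1653 peaks, and 1375 of the conservative peaks were also in it. Replicate 1 had 1450 thresholded peaks and replicate 2 had 1908. Their ranked lists, which include weak peaks, held 52143 and 37242. The depth of the libraries was unknown, so these numbers do not measure how much was bound. The signal of each peak is the authors' own value.

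The strongest Ravus-eGFP peak lay at Ugalt, which encodes a UDP-galactose transporter. It spanned 2703744 to 2704031 on X, an interval that includes the Ugalt start site. Its summit lay outside any annotated gene, 36 bp upstream of that start site. Its signal was 1414 in the conservative list, and it ranked 1 in each replicate, with values of 588 and 836.5. The 61 bp around its summit, from 2703858 to 2703918, read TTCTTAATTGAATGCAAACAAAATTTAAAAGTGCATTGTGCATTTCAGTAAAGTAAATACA. The next peaks lay 89 bp upstream of CG14100 on 3L, with a signal of 1170, and in an intron of CG11050 on 2L, with a signal of 1169.

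The peak 146 bp upstream of mRpL41, a protein of the large mitochondrial ribosomal subunit, spanned 15217600 to 15217890 on 2R and had a signal of 1133. The peak at PNPase, the mitochondrial polynucleotide phosphorylase, had its summit 79 bp inside the gene and a signal of 898. Tcs5, which acts in tRNA modification, had a peak 98 bp upstream with a signal of 903. Art3, an arginine methyltransferase gene, had an upstream peak with a signal of 845, and the same peak lay 132 bp from the start site of mRpS10. A peak between CenG1A and mRpS23 had a signal of 780.5.

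The Polycomb group gene ph-p had a promoter peak on X with a signal of 873. Its summit lay inside the gene, 497 bp upstream of the nearest ph-p start site. Chro, which encodes the chromosomal protein Chromator, had a peak 78 bp inside the gene with a signal of 829. Introns of Adf1, a MADF-BESS domain transcription factor gene, and Trl, the gene of GAGA factor, held peaks with signals of 797 and 666.5. A peak in an intron of the overlapping HmgD and HmgZ genes, 565 bp upstream of the nearest HmgZ start site, had a signal of 755. The others lay nearest to CG7601, asRNA:CR45928, CG5611, lncRNA:CR44619, CG32772, lncRNA:CR45643, CG18549, CG9147, CG13323, px, CG13390 and Fkbp14. Of the 25 peaks, 18 were at promoters, 5 in introns and 2 in intergenic sequence, and their signals ranged from 663.5 to 1414. All 25 ranked within the top 50 of both replicates, the lowest at rank 32.

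Ravus-eGFP sites were largely shared by the replicates. Of the 1450 peaks of replicate 1, 1196 overlapped a peak of replicate 2, or 82.5% (95% interval 80.4 to 84.4%). Of the 1908 peaks of replicate 2, 1200 overlapped a peak of replicate 1, or 62.9% (60.7 to 65.1%). Random placements gave 0.774% and 0.593%, and both p were 0.001, the smallest possible. The matched peaks of replicate 1 had a median signal of 64.4, against 42.2 for the unmatched. Of the unmatched peaks, 86.6% in replicate 1 and 88.7% in replicate 2 were found in the other replicate's ranked list. The ranked lists covered 15283 kb in replicate 1 and 10738 kb in replicate 2. No share from random placements was computed for this comparison, so part of it can arise by chance.

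At conservative peaks the replicates also ranked sites alike. Over the 1467 of 1472 peaks with a match in both ranked lists, Spearman's rho of the log2 signal was 0.799 and Pearson's r was 0.882, each with a permutation p of 1e-05, the smallest possible. This relation is across peaks, which are not independent replicates, and the list was built from sites found in both libraries. Signal in replicate 2 lay above that in replicate 1 by a median of 0.39 on the log2 scale (SD 0.37 over peaks), on a scale not given in the sources used here. Summits lay a median of 17 bp apart. Of the strongest 100 peaks of replicate 1, 85% overlapped one of the strongest 100 of replicate 2 (76.5 to 91.3%), and of the strongest 1000, 78.6% did (75.9 to 81.1%).

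Promoters were the main class of Ravus-eGFP sites. They held 767 of the 1472 summits, or 52.1% (49.5 to 54.7%), against 13.6% ± 0.880 (SD over 1000 random placements), a ratio of 3.83. Coding sequence held 2 summits, or 0.136% against 13.7% at random, and 3' UTRs held 10, or 0.679% against 4.47%. Intergenic sequence held 10.2% against 27.1%. Introns held 520 summits, or 35.3% against 39.5%, and this class alone no longer differed when low-ranked peaks were the background. Each of these 5 classes reached the smallest p that the placements can give, which adjusted to 0.00280. For 5' UTRs, with 7 summits, and other exons, with 16, no difference was detected (adjusted permutation p = 0.259 and 0.320).

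**Figure D1:**
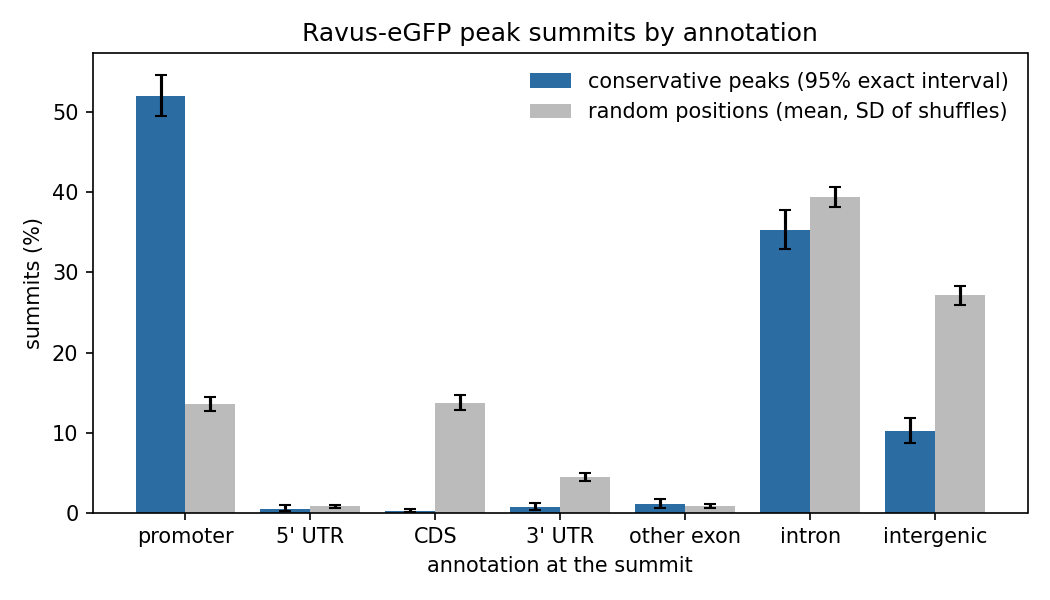
Share of summits in percent for each annotation class on the horizontal axis, for the 1472 conservative peaks (blue, error bars exact 95% intervals) and for random positions (grey, mean and SD of 1000 placements). Promoters held 52.1% of the summits against 13.6% at random, and coding sequence 0.136% against 13.7%.

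Promoter peaks lay upstream of the start site rather than over it. Of the 767 promoter summits, 658 were upstream of the nearest start site, or 85.8% (83.1 to 88.2%; exact binomial p = 1.86e-96, two-sided). Their median position was -134 bp, with quartiles of -217 and -76 bp. The fullest bin of 50 bp, from -150 to -100 bp, held 164 summits, whereas the 50 bp downstream of the start site held 19.

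**Figure D2:**
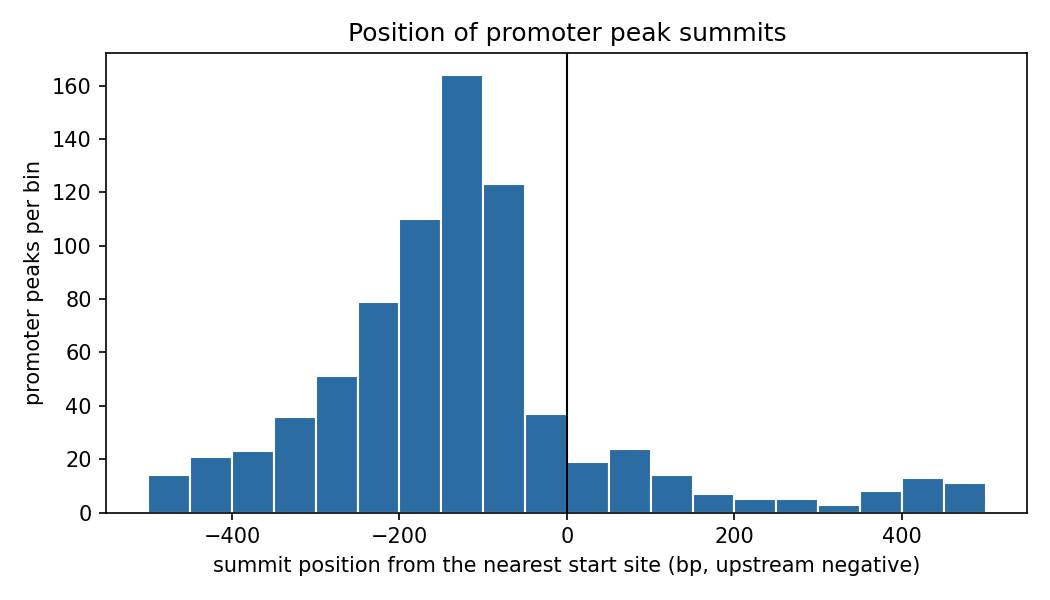
Number of promoter summits per bin of 50 bp (vertical axis) by distance in bp from the nearest start site, upstream negative (horizontal axis), for the 767 promoter peaks of the conservative list. The bin from -150 to -100 bp was the fullest, with 164 summits.

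Promoter sites carried the higher signal. The median signal was 142 at the 767 promoter peaks (quartiles 105 and 216) and 120 at the 532 distal peaks (94.8 and 164). The ratio was 1.19, with a permutation p of 2e-05, two-sided. Promoters made up 63.9% of the 368 peaks with the highest signal (58.7 to 68.8%) and 43.8% of the 368 with the lowest (38.6 to 49.0%).

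The X chromosome held more Ravus-eGFP sites than its length gives. It had 306 peaks where 252 were expected, a ratio of 1.21 (adjusted exact binomial p = 9.63e-04), and the ratio was 1.27 by the number of start sites (adjusted p = 7.31e-05). Both expectations count all arms, including Y, where no peak was found, and this raises the ratio for X. Measured by arm length, the excess lay away from promoters. Distal peaks on X numbered 130 against 94.0 expected, a ratio of 1.38 (adjusted exact p = 2.47e-04), whereas promoter peaks numbered 135 against 136 expected, a ratio of 0.992 (adjusted exact p = 0.962). Promoters made up 44.1% of peaks on X (38.5 to 49.9%) and 54.3% on the autosomes (51.4 to 57.2%; two-sided Fisher's exact p = 0.00162). This division of X peaks by class was chosen after the excess had been seen.

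Chromosome 4 and Y held few sites. On 4 there were 4 peaks where 14.4 were expected by length (adjusted exact p = 0.00512), a ratio of 0.277. The ratio was 0.143 without replicate 2, and the call was lost among the 737 peaks with the higher signal (0.416). On Y there were 0 peaks where 39.25 were expected by length (adjusted exact p = 7.25e-17) and 6.90 by start sites (adjusted exact p = 0.00625), but repeats limit how much of Y short reads can be placed on. For 2L, 2R, 3L and 3R the ratios to the expectation from length were 1.11, 0.987, 1.01 and 0.909, none past the threshold (adjusted p from 0.0784 to 0.897). Calls appeared for 2R against the number of start sites (0.879, adjusted exact p = 0.0418), for 2L without replicate 2 (1.16, 0.0145) and for 3R without replicate 1 (0.892, 0.0163).

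A total of 1075 genes had a conservative summit within 500 bp of a start site, and 991 of them were protein-coding, 7.09% of 13968. Genes of cytoplasmic ribosomal proteins were bound more often than other genes, with 15 of 85, or 17.6% against 7.03% (odds ratio 2.83, adjusted Fisher's exact p = 0.00536). RpL7, RpL34b, RpL32 and RpS27 had the strongest of these peaks, with signals from 170 at RpS27 to 216 at RpL7. The odds ratio was 4.90 without replicate 1. The call was lost without replicate 2 (odds ratio 2.20), among the peaks with the higher signal (1.86) and against genes with a ranked promoter peak (1.97). Of the mitochondrial ribosomal protein genes, 8 of 73 were bound (adjusted Fisher's exact p = 0.594), among them mRpL41, mRpS10, mRpS23 and mRpL23, whose signals were between 653 and 1133.

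Heat shock protein genes had 5 of 19 members bound (odds ratio 4.70, adjusted Fisher's exact p = 0.0448). Hsp27 had a signal of 372. Hsc70-5, Hsc70-4 and Hsp26 lay between 101 and 121, and none of them had a promoter peak among the peaks with the higher signal. Hsp26 had none without replicate 2 either. The call for the heat shock list stood close to the threshold. It was lost when either replicate was left out (3.70 without replicate 1 and 3.56 without replicate 2), with the 1000 bp window (3.92), with the nearest start site at any distance (4.15), among the peaks with the higher signal (1.35), and against genes with a ranked promoter peak (4.91).

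Replication-dependent histone, tRNA and snoRNA genes had a promoter peak less often than other genes. Replication-dependent histone genes had 0 of 111 bound (adjusted Fisher's exact p = 0.00493), tRNA genes 3 of 290 (odds ratio 0.165, adjusted p = 0.00107) and snoRNA genes 4 of 269 (odds ratio 0.239, adjusted p = 0.00493). The tRNA genes bound were tRNA:Tyr-GTA-1-8, tRNA:Asp-GTC-1-4 and tRNA:Asp-GTC-1-5, the last pair by the same peak. The snoRNA genes bound were snoRNA:Or-ACA6, snoRNA:Or-aca5, snoRNA:Psi28S-2949 and snoRNA:Or-CD11a, and 1 peak served both snoRNA:Or-aca5 and snoRNA:Psi28S-2949. None of these 4 had a promoter peak without replicate 2, and snoRNA:Or-aca5 and snoRNA:Or-CD11a had none without replicate 1. In the further series list and among the peaks with the higher signal only snoRNA:Or-ACA6 kept its peak. The odds ratio of snoRNA genes was 0.142 without replicate 1 and 0.0604 without replicate 2. That of tRNA genes was 0.312 with the 1000 bp window and 0.431 by the nearest start site. For snRNA genes, with 0 of 32 bound, no difference was detected (adjusted Fisher's exact p = 0.594). The snoRNA call was lost with the 1000 bp window (0.970) and against genes with a ranked promoter peak (0.314), and the histone call was lost in that last background and among the peaks with the higher signal. Histone and tRNA genes occur in near-identical copies, where the placing of reads is uncertain, and so are their counts. The tests also treat each copy as an independent gene, which overstates the number of separate sites where copies lie together.

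Several members of the chromatin regulator lists had strong peaks, but by promoter peaks these lists did not pass the threshold. Of the Polycomb and trithorax group genes, 4 of 22 were bound (adjusted Fisher's exact p = 0.225). These were ph-p, brm, an ATPase of chromatin remodelling with a signal of 434, E(z), the histone H3 lysine methyltransferase with 264, and Trl with 142. With the nearest start site at any distance, the Polycomb and trithorax list passed (odds ratio 5.43, adjusted Fisher's exact p = 0.00963, against 2.92 by promoter peaks). Of the insulator protein genes, 3 of 14 were bound (adjusted Fisher's exact p = 0.225), namely Chro, Cp190 with a signal of 275, and Trl. Of the MADF-BESS domain genes, 3 of 10 were bound (odds ratio 5.63, adjusted Fisher's exact p = 0.122), namely brwl with a signal of 391, hng3 with 156, and Ravus. The MADF-BESS list passed the threshold with the 1000 bp window (odds ratio 7.31), with the nearest start site (7.75) and without replicate 1 (6.91). Without replicate 2 its odds ratio was 3.33 (adjusted Fisher's exact p = 0.379). Ravus is the tagged gene, and its peak counts toward each of these calls but is absent without replicate 2. The list was not tested without Ravus.

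There was no bound member by promoter peak among the 8 Hox genes, 15 pair-rule and segment polarity genes, 12 dorsoventral patterning genes, 14 proneural genes, 7 gut and yolk markers, 12 hemocyte markers, 11 epidermis markers and 23 germline genes, and no difference from other genes was detected in any of these lists. By the nearest start site at any distance the odds ratios were 1.66 for Hox, 1.78 for pair-rule and 1.05 for dorsoventral genes. They were 1.05 for hemocyte, 4.35 for epidermis, 4.65 for muscle and 5.80 for tracheal markers, and none of these passed the threshold. Without replicate 1, the odds ratio was 1.55 for germline genes and 0.940 for hemocyte markers. Among other developmental genes, bcd, the anterior determinant, had a peak with a signal of 113. The neuronal RNA-binding protein gene elav had one with 308.5, the heart regulator gene tin 204, sls 146 and trh 94.6. Of the proteasome genes 2 of 48 were bound, Rpn3 and Prosbeta2. Rpn3 had no promoter peak without replicate 2, and Prosbeta2 had none in either replicate's own list, which gave odds ratios of 0 and 0.219 without replicates 2 and 1, against 0.569. Of the respiratory chain genes 5 of 88 were bound, with ND-ASHI, ND-MWFE, ND-51 and ATPsynE the strongest. Among cell cycle genes 1 of 31 was bound, Dp. The odds ratio of this list was 0.436, against 0.917 without replicate 2 and 0.7125 without replicate 1. None of the lists in this paragraph passed the threshold.

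Ravus-eGFP summits were AT-rich. GC content was 30.5% ± 8.49 (SD, n = 1472) in the 101 bp at the summit and 44.3% ± 7.03 in the flanks, a difference of -13.8 percentage points (95% interval -14.4 to -13.2; permutation p = 1e-05, the smallest possible). The summit had the lower GC in 89.1% of the peaks. Promoter peaks stood at 30.1% ± 9.06 (n = 767) and distal peaks at 30.7% ± 7.65 (n = 532). Peaks of low rank that overlapped no thresholded peak went the other way, with GC higher at the summit by 3.595 points. Random positions had 42.9%.

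**Figure D3:**
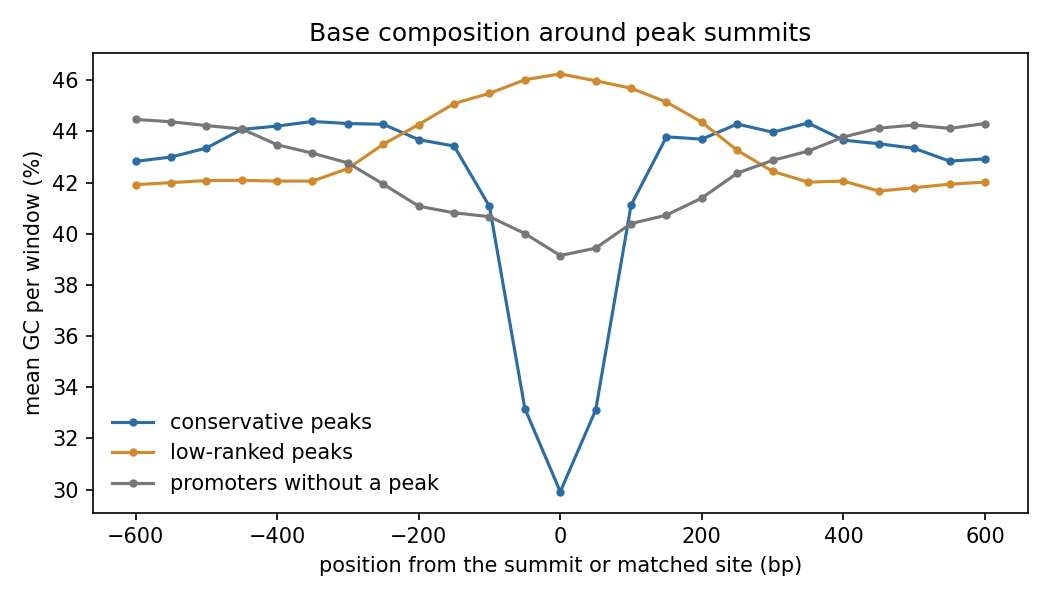
Mean GC in percent (vertical axis) of windows of 51 bp every 50 bp around the summit in bp (horizontal axis), for the 1472 conservative peaks (blue), 5028 low-ranked peaks (orange) and 1534 positions at promoters without a peak (grey), on an axis that starts above 0. The conservative peaks dip to 29.9% at the summit, where the low-ranked peaks stand at 46.2% and the unbound promoters at 39.1%.

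Motif frequency differed between summits and flanks. The TATA box sequence TATAAA stood in 27.0% of summit windows and 9.78% of flanks (odds ratio 3.41, adjusted Fisher's exact p = 6.55e-46), and the Caudal consensus TTTATK in 45.7% and 25.9% (2.40, 5.21e-38). The AT repeat ATATATAT (3.28), the Su(Hw) core (3.88), the Ohler motif 6 core (3.52) and the CTCF core (3.45) were also more frequent at summits. GAGA (0.181), the Adf1 consensus (0.0817), CA repeats (0.0585) and the E-box (0.444) were less frequent, which makes 10 of 20 motifs past the threshold. Leaving out 1 library moved some of these values, with the Su(Hw) core at 2.12 and GAGA at 0.345 without replicate 1, and CA repeats at 0.0357 without replicate 2. Against genome windows of equal GC, TATAAA stood at an odds ratio of 0.997 and 1 motif passed, the CTCF core, present in 12 of 1472 summit windows and 10 of 14711 others (odds ratio 12.1, adjusted Fisher's exact p = 1.67e-06). The CTCF call against the flanks was lost without replicate 2 (2.62), among the peaks with the higher signal (2.00), in windows within 100 bp (2.01) or 25 bp (2.00) of the summit, and against promoters without a peak (1.00). Within 25 bp of the summit and against promoters without a peak, the calls for the Ohler motif 6 core (2.00 and 1.17) and the E-box (0.574 and 0.560) were also lost, as was that for the AT repeat against those promoters (1.74).

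Short sequences of A and T were more frequent at summits. Of 32896 8-mers, 753 were more frequent at summits and 197 less frequent, and TATTTTAA led with 8.22% of summit windows against 1.49% of flanks (adjusted Fisher's exact p = 6.66e-22). Of the 136 8-mers made of A and T alone, 133 were among the more frequent. Of 2080 6-mers, 400 were more and 926 less frequent, and TTAAAA led with 40.5% against 14.0%. Against windows of equal GC, 9 8-mers were more frequent and 0 less, and 28 6-mers were more and 7 less frequent. TATTTTAA was among these 9, with 8.22% of summit windows against 5.11% of the others (adjusted Fisher's exact p = 0.0177). TTAAAA was among the 28, with 40.5% against 34.4% (adjusted Fisher's exact p = 0.00144).

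The Ravus gene itself lay beside a peak. Ravus (FBgn0038128) spans 13262733 to 13264061 on the minus strand of 3R, and the conservative peak from 13263994 to 13264303 had its summit at 13264149. This is 88 bp upstream of Ravus and 215 bp from the start site of Su(var)3-7, a heterochromatin protein gene on the other strand. Its signal was 91.3, rank 1246 of 1474, and it was the only conservative peak within 50 kb. The peak was in the thresholded list of replicate 2, with a signal of 53.3, but not in that of replicate 1, whose ranked list held it at rank 1984 with 32.9. The 61 bp at the summit, from 13264119 to 13264179, were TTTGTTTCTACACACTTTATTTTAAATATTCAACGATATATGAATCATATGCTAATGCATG. The labels do not say where the tagged copy was inserted, and a peak list cannot tell it from the native gene.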

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

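Of the tests given here, that of the base composition of the excluded peaks and their return to the conservative list were chosen only after related results had been seen.

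Signal appeared in peaks outside the lists on which the comparisons rest, although those left out of the conservative list were added back as an alternative for the promoter share (51.8%) and the gene lists (5 passing). The ranked lists held peaks within the IDR limit of 0.01 that the matching thresholded list left out. There were 41 for the conservative list, 50 for the further series list, 66 for replicate 1 and 46 for replicate 2. The 41 had a median signal of 130, against 132 for the retained peaks. The strongest, on 2L from 480949 to 481230 in an intron of ush and nearest to cbt, had a signal of 1211, which would rank it 2 among all. Others lay at Lk6 (699), larp (511), trx (483) and Kdm2 (231, 220 and 174). These genes were chosen after their values were seen. Of the 41, 24 were on 3R, 12 on 2L and 0 on X.

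Signal in repeats is argued against, since 25% of the 40 excluded summits on the arms lay in soft-masked sequence or a transposable element insertion (95% interval 12.7 to 41.2%), against 28.9% of the retained ones. Background sites unlike the retained peaks are argued against as well, because the excluded peaks had a GC difference from summit to flank of -15.4 percentage points (-18.8 to -12.0). A fixed set of excluded regions remains a candidate explanation, since 2.5% of them, 1 of 40, overlapped a retained peak of any thresholded list, whereas 98.5% of the retained peaks were found in another list. All 40 were present in the ranked lists of both replicates, which says little, since the series ranked lists were made from both. The undescribed further input of the thresholded lists was not analysed here. No biological explanation was tested, because the study has 1 group.

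Replicate 1's thresholded list also held 25 peaks outside the chromosome arms, with a median signal of 46.8, of which 6 were found in the ranked list of replicate 2, whose thresholded list held 0 such peaks.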

How the results depend on the processing

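The backgrounds of equal GC, the low-ranked peaks as a comparison for base composition, the return of excluded peaks and the settings for the Ravus locus were chosen only after the results were seen. A tested value was compared by its side of the threshold, and by its direction where it passed in either setting; a count was compared within 1.5 times, and the rank agreement within its interval. By these rules 707 of 802 alternative values for 142 results were alike, 29 lost a call, 13 gained one, 45 moved and 8 changed direction. A change of direction needed a call in only 1 of the settings, so it need not be a reversal. Of the 8, the 5 against windows of equal GC were lost calls. Over the main results, which include single gene lists and motifs, 122 of 158 were alike. Calls held under every alternative run for replicate overlap (73.9 to 88.4% for replicate 1 and 56.1 to 76.1% for replicate 2), signal correlation (rho 0.743 to 0.800), promoter share (39.5 to 63.9%), the X ratio (1.18 to 1.27) and the promoter to distal signal ratio (1.13 to 1.24). Among the peaks with the higher signal, which are fewer by construction, there were 737 peaks, 2 gene lists passed, the odds ratios were 1.859 for ribosomal, 0 for histone and 1.353 for heat shock genes and 2.005 for the CTCF core, 8-mers numbered 274 higher and 24 lower, and the Ravus locus held 0 peaks. Against genes with a ranked promoter peak, 1 list passed, with 1.97 for ribosomal, 0 for histone, 0.3141 for snoRNA and 4.909 for heat shock genes. The 1000 bp promoter window gave 0.9695 for snoRNA and 3.915 for heat shock genes, and the nearest start site gave 4.151 for heat shock genes and brought the Polycomb and trithorax list past the threshold at 5.434 (adjusted Fisher's exact p = 0.00963), with 6 lists passing. Within 100 bp of the summit the CTCF core stood at 2.012 and the BEAF-32 core turned to 1.238 and passed the threshold (adjusted Fisher's exact p = 0.00755), DRE (1.807), Ohler motif 7 (1.862) and the initiator (0.7618) passed as well, for 13 motifs in all, and 8-mers numbered 1312 higher and 814 lower. Within 25 bp the CTCF core stood at 2.003, and against promoters without a peak at 1, where the BEAF-32 core passed in the opposite direction at 0.6174 (adjusted Fisher's exact p = 6.43e-04). With low-ranked peaks as background 339 8-mers were lower, and in those peaks GC rose to the summit by 3.595 points. Against windows of equal GC 1 motif passed. The calls for GAGA (1.335), E-box (1.543), TATA box (0.9974), Caudal (0.9907) and the AT repeat (0.9685) were lost there. These odds ratios fell on the other side of 1, but none passed the threshold. In that background 6-mers stood at 28 higher and 7 lower and 8-mers at 9 and 0. This background removes composition by construction. Leaving out a replicate gave 3 to 5 gene lists, odds ratios of 2.201 to 4.898 for ribosomal genes, 3.556 to 3.703 for heat shock genes and 2.615 to 3.019 for the CTCF core, 0.9464 to 1.235 for the BEAF-32 core, which passed at the higher value, without replicate 1 (adjusted Fisher's exact p = 0.0253), and 0 to 1 peaks at the Ravus locus. Without replicate 1, Zelda (0.3316) and Bicoid (1.628) also passed. Of the named genes, the 25 strongest peaks were present in the further series list and in each replicate's own list, and of 40 list members 32 to 37 had a promoter peak there; among the peaks with the higher signal 25 members did. For the other changes the cause was not tested. No paired analysis was possible because the study has 1 group. Unknown depth limits any statement about sites without a peak.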

Other observations

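Chosen only after the results were seen were the tests of base composition alone and of the 8-mer at other peaks, the background of equal GC, the reading of the odds ratio for X promoters, and the bounds used to weigh the start site ratio of X, a ratio whose computation was fixed beforehand.

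Ravus-eGFP peaks also gathered at divergent promoters. Of 2232 regions between start sites that face away from each other within 1000 bp, 205 held a conservative summit, or 9.19%, against 282 of 9401 single upstream regions, or 3%. That divergent pairs hold peaks more often than their number of start sites gives was tested as a hypothesis, with a bound of 2 on the ratio; it was 3.06 (95% interval 2.57 to 3.64). Peaks also lay near each other, with 9.72% within 1000 bp of another summit against 2.22% for random placements (permutation p = 0.002, the smallest possible). The placements ignored start sites, so part or all of this nearness can follow from the concentration of summits at promoters. Annotated transposable element insertions held 3 summits, or 0.204%, against 5.86% of random positions, although reads from repeats are hard to place. The share of protein-coding start sites with a peak fell with GC of the upstream window, from 12.4% (10.8 to 14.2%) of 1515 in the class of lowest GC to 3.76% (2.82 to 4.91%) of 1382 in the highest.

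A base composition bias that makes all peak summits AT-rich is argued against. Low-ranked peaks of the same lists had GC higher at the summit by 3.595 percentage points (3.24 to 3.96). Those peaks were not matched for annotation class and lay more often in coding sequence (adjusted Fisher's exact p = 1.46e-104). The comparison therefore cannot decide on a bias at sites like those of the conservative list. Ordinary composition upstream of start sites is argued against, because promoters without a peak had 9.12 points more GC at the same distances (8.28 to 9.95). GC content alone, with no preferred order of bases, is argued against as the whole cause by 9 8-mers enriched over windows of equal GC. This lies between the bounds of 0 and 20 set for the test, and the reading rests on the recurrence of the leading 8-mer at other peaks. Those windows were drawn without regard to start sites, so an order of bases common to promoters cannot be told apart. The 8-mers were not compared with promoters without a peak. A preference of the tagged protein or its partners for AT-rich DNA may remain as a hypothesis found and tested on the same data. An effect of the antibody or of open chromatin stays open, as neither control values nor accessibility were analysed here.

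The number of start sites does not account for the excess of peaks on X, since X held 16.4% of start sites and 17.1% of the length. The ratio to start sites, 1.27, thus had to lie above the ratio to length, and it is no separate test. A test of the base composition of X promoters cannot decide on this excess. The test used start sites of protein-coding genes, whereas by arm length the excess lay at distal peaks. The Mantel-Haenszel odds ratio of a bound start site on X across 10 GC classes was 0.763 (0.617 to 0.944). The base composition of distal sequence on X was not tested. The bound set for this test had assumed an excess at X promoters, which was wrong, because before grouping by GC the odds ratio was already 0.731. Stronger signal on X that lifts more peaks over the limit cannot be told apart from other causes: X held 0.6565 of the low-ranked peaks expected from its length, and median signals were 134 on X and 131 on the autosomes. What keeps it open is that the sex of the embryos and the depth of the control over X are unknown; no biological explanation was tested.

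The 8-mer CACTGTGC (reverse complement GCACAGTG) had the smallest p against windows of equal GC, in 19 of 1472 summit windows and 20 of 14711 others (adjusted Fisher's exact p = 1.13e-05). With 2 windows per peak, 7 of 20 draws called 1 8-mer and the other draws called 0, so the call varied with the draw. Of the 8 8-mers that led a draw, 6 held the core CACTG on either strand, and they led 17 of the 20 draws; 7 of the 9 8-mers enriched over the larger background held it too, as did 5 of the 28 6-mers. This core was noticed after the values were seen and was not tested on its own. The hypothesis that this sequence preference recurs outside the conservative list was tested at 727 thresholded peaks that overlap no conservative peak. There 14 held it, against 16 of 7270 windows of equal GC, an odds ratio of 8.90 (4.004 to 19.5) with a one-sided Fisher's exact p of 8.51e-08. These peaks come from the same libraries and carry the same difference in soft-masked sequence. The windows were also not matched for distance to start sites. A sequence preference would give this result, but an order of bases common to promoters cannot be told from it. It does not show that Ravus binds the 8-mer. The 8-mer could account for few sites, as 1.29% of the summit windows held it. TATTTTAA, which lacks the core, was also enriched over windows of equal GC, at 8.22% of summit windows against 5.11%. Its recurrence at other peaks was not tested.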
